A study of Caenorhabditis elegans with 6 samples.

How the data were processed

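RNA was measured in whole animals of the wild-type Caenorhabditis elegans strain N2. Per the labels' protocols, animals were raised at 20 °C on Escherichia coli OP50, the standard laboratory food, to the late L4 or young adult stage. They were then washed and moved to a lawn of E. coli OP50, Pseudomonas aeruginosa z11 or P. aeruginosa PA14, and RNA was taken after 22 h. Total RNA was extracted with Trizol and a column concentrator and made into paired-end cDNA libraries. There were 3 groups of 2 libraries each. The labels number the libraries within a group but do not say whether they came from separate cultures, so every p-value measures only the spread between these samples, which may be technical. In each group the 2 libraries differed by far more than counting noise (chi-square per gene of 77.9 for OP50, 35.4 for z11 and 12.4 for PA14), and both were kept.

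The authors deposited 1 table per library with estimated counts and TPM, a length-scaled abundance, for 31800 transcripts, together with the length and effective length of each transcript. The submitters' processing notes name kallisto, which assigns reads to transcripts without base-level alignment, and DESeq2; their versions, the annotation release and the genome build are not given in the sources used here. The deposited estimated counts need not be whole numbers, and the deposited TPM values sum to the same total in each library. Of the transcript names, 31770 matched the Ensembl annotation of assembly WBcel235, from which gene names and coordinates were taken, and 30 did not. Estimated counts were summed per gene, giving 19987 genes, and rounded to whole numbers. Transcripts that are nearly identical between genes share reads, so values of close paralogs and duplicated genes are uncertain; the 2 copies of hsp-16.48 had the same values. The sources used here do not say whether the libraries kept strand.

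Total estimated counts were 23572771 and 39797661 for OP50, 31805930 and 16758601 for z11, and 19052010 and 21549530 for PA14. Genes passing edgeR's filterByExpr numbered 14543, and the others held 0.0487% of the counts. Normalised counts are CPM after TMM scaling. Each comparison was tested with edgeR's quasi-likelihood test (glmQLFit and glmQLFTest) on all 6 libraries, which share 1 estimate of the spread with 3 residual degrees of freedom. Genes with a Benjamini-Hochberg adjusted p under 0.05 are described as called. Standard errors of log2 fold changes were taken from the F statistic and are approximate. Values are mean ± SD over 2 libraries. With 2 against 2 libraries a single gene could not reach a permutation p under 0.05, so the calls rest on the model.

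A gene was PA14-distinct when it was called in the same direction against OP50 and against z11, and z11-distinct when it was called in the same direction against OP50 and against PA14. In all, 36 gene lists were fixed before the data were examined, and 7 of their symbols were not found in the annotation. Lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation. Under the latter no list was called in any comparison. It rests on the 3 residual degrees of freedom, so it has less power here than the preset one. For a simulated list of 20 genes raised 2-fold, camera gave p = 0.00106 with an estimated correlation and 5.29e-31 with the preset one. For infection response genes on PA14 against OP50 the estimated correlation was -0.0385, yet camera's p went from 4.52e-16 to 0.0031. Of 100 simulated lists without change, 0 had p under 0.05 with an estimated correlation, and 6 with the preset one. The simulated genes were drawn independently, so these counts do not give the error rate of either test for correlated genes. Lack of a call with an estimated correlation thus neither shows nor excludes that correlated genes explain a preset call. fry, which asks whether the genes of a list move on balance in 1 direction, was an alternative. Gene families, taken from the letters of the gene names and with at least 10 tested members, were tested for over-representation with Fisher's exact test in 136 families. Named genes were the 8 with the highest and the 8 with the lowest log2 fold change among called genes whose groups did not overlap and whose higher group had at least 10 CPM. To these were added up to 4 members per list with the smallest p, a fixed set of response genes, and the 8 leading genes of each class and direction. Chosen after their values were seen were the genes called in opposite directions by the 2 strains.

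The tests were tried on simulated counts drawn from the means of these 14543 genes, with 200 genes changed. For PA14 against OP50, edgeR recovered 51% of genes changed 2-fold and 91% of those changed 4-fold, and 3.4% of its calls were false. For z11 against OP50 it recovered 54% and 91%, with 5.84% false calls. For PA14 against z11 it recovered 55% and 90%, with 9.94% false calls, above the rate of 0.05 the threshold aims at. Alternatives fixed in advance were DESeq2 size factors, library size alone, the DESeq2 Wald test, no filter, a filter at 10 CPM in 2 libraries, an effective length offset, limma on log2(TPM + 1) and log2(TPM + 0.1), a replicate block, a threshold of 0.01, a requirement of a doubling or halving, only the 2 groups compared, and each library left out. A covariate of mean fragment length, and counting genes of a family with identical counts once, were added after seeing the data. Work was done in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.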

Results

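The data are gene-level counts from 6 whole-animal libraries of wild-type C. elegans, 2 each from animals kept on E. coli OP50, P. aeruginosa z11 or P. aeruginosa PA14. Totals ranged from 16758601 to 39797661 estimated counts. PA14 is a widely used virulent isolate. The series title names a within-species control, and the z11 group allowed the response to PA14 to be set against another strain of the same species. The first principal component of log2 CPM held 60.2% of the variance and separated PA14 from the other groups; the second held 23.8% and separated OP50 from z11. The next, with 8.98%, separated the libraries within each group.

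**Figure D1:**
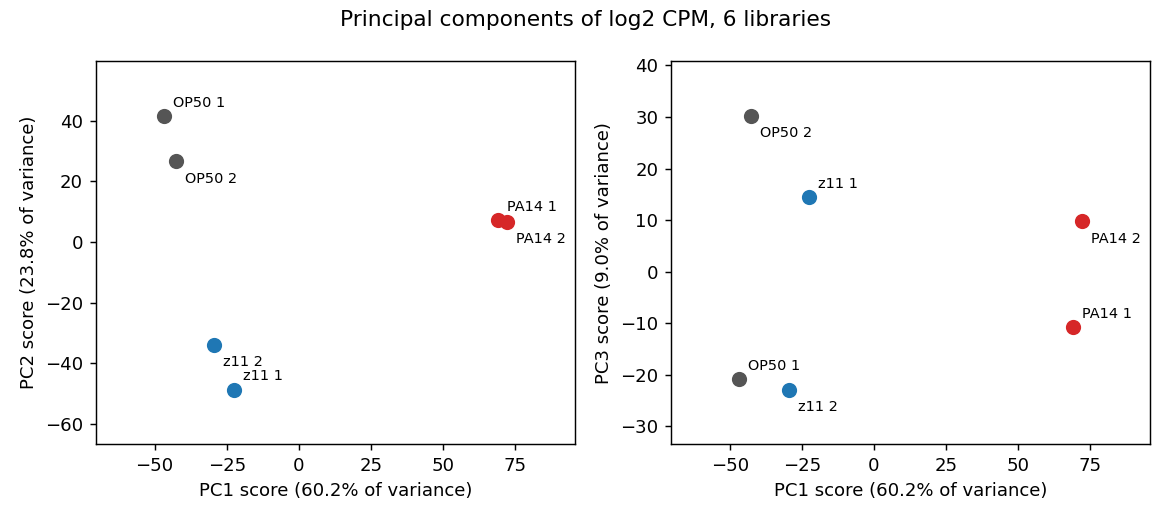
Principal component scores of log2 CPM for the 6 libraries, with the first component on both horizontal axes and the second or the one after it on the vertical axes. Each point is 1 library; the first component, 60.2% of the variance, places both PA14 libraries apart from the other 4.

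The first comparison asked which genes differed between animals on PA14 and on OP50. On PA14, 16 of 18 genes known to respond to infection rose, while 5 of 7 propionate shunt genes, 10 of 15 methionine cycle genes and 39 of 120 collagens fell. Camera called these 4 lists, but none with an estimated correlation (adjusted p = 0.111, 0.407, 0.287 and 0.509). The infection response gene irg-1 (chromosome V, 3523587 to 3524679, WBcel235) went from 1.18 ± 0.256 to 179 ± 3 CPM, a log2 fold change of 7.28 (SE 0.222, adjusted p = 1.26e-06, n = 2 per group). The CUB-like domain gene dod-24 (chromosome IV, 12940106 to 12941354) rose from 14.2 ± 1.13 to 3052 ± 239.9 CPM, and the nearby cld-1 (chromosome IV, 12935011 to 12936271) from 7.89 ± 2.97 to 2649 ± 11.9 CPM. The acyl-CoA dehydrogenase acdh-1 (chromosome I, 6497436 to 6499560), the first enzyme of the propionate shunt, fell from 1922 ± 244 to 18.9 ± 8.4 CPM, a log2 fold change of -6.66 (SE 0.348, adjusted p = 6.1e-06). In all, 1940 genes were higher and 1068 lower on PA14 among 14543 tested; 1402 were at least doubled and 629 at least halved.

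Of the 18 infection response genes, 16 rose and 1 fell on PA14, and 17 and 1 when adjusted over the list alone; camera called the list, with an adjusted p = 0.111 with an estimated correlation. The log2 fold changes included 5.39 (SE 0.241) for irg-5, 3.68 (SE 0.208) for irg-4, 4.93 (SE 0.276) for sysm-1 and 5.49 (SE 0.209) for the lysozyme lys-2. Of 122 C-type lectins, sugar-binding proteins of which many are secreted, 52 rose and 15 fell (55 and 17 adjusted over the list alone; adjusted p = 0.313 with an estimated correlation). clec-4 rose by a log2 fold change of 6.29 (SE 0.191), and clec-47 went the other way, at -4.36 (SE 0.256). Of 120 F-box genes of the fbxa family, 65 rose and 1 fell (70 and 3 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation): fbxa-128 rose by 4.36 (SE 0.195) and fbxa-74 by 3.65 (SE 0.17), while fbxa-72 was at -3.65 (SE 0.212). Of 187 nuclear hormone receptors 67 rose and 7 fell (74 and 10 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation), among them nhr-99 at 3.41 (SE 0.208) and nhr-114 at -3.41 (SE 0.2). All 3 of these families were over-represented among the higher genes in Fisher's exact test, with fbxa at 65 against 16.01 expected, clec at 52 against 16.27 and nhr at 67 against 24.95.

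Among the lower genes, 5 of the 7 propionate shunt genes fell and none rose on PA14 (6 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation). hphd-1 had a log2 fold change of -4.46 (SE 0.195), ech-6 of -2.87 (SE 0.168) and the regulator nhr-68 of -2.32 (SE 0.215). In the list of 15 methionine and S-adenosylmethionine cycle genes, 10 fell and 2 rose (11 and 3 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation). The folate transporter gene folt-2 was at -4.60 (SE 0.192), the S-adenosylmethionine synthetase gene sams-1 at -2.55 (SE 0.174), metr-1 at -1.55 (SE 0.191), and pmt-1 rose by 0.73 (SE 0.146). Of 120 collagens, 39 fell and 5 rose (44 and 7 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation), with col-80 going from 1532 ± 105 to 201 ± 19.8 CPM and col-93 from 1875 ± 179 to 190.4 ± 24.8 CPM. Of 15 intestine markers, 9 rose and 1 fell (10 and 1 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation): the intermediate filament gene ifb-2 rose by 2.07 (SE 0.164), and the metallothionein gene mtl-2 was at -2.70 (SE 0.234). Of 25 germline and oocyte genes, 3 fell, glh-1, perm-2 and perm-4 (3 adjusted over the list alone; adjusted p = 0.758 with an estimated correlation). Of 13 mitochondrial unfolded protein response genes 1 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation), and its chaperone gene hsp-6 was not called (-0.65, SE 0.251, adjusted p = 0.12). Of 17 endoplasmic reticulum unfolded protein response genes 2 rose and 1 fell (2 and 1 adjusted over the list alone), camera did not call the list (adjusted p = 0.922), and hsp-4 was not called (-0.48, SE 0.232, adjusted p = 0.216). Of 13 heat shock genes on the fixed list 4 fell (4 adjusted over the list alone), 2 of them identical copies of hsp-16.48, and camera did not call it (adjusted p = 0.0646, and adjusted p = 0.407 with an estimated correlation). 
Of 56 oxidative stress and glutathione genes 19 rose and 4 fell (20 and 4 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation): the glutathione transferase gene gst-38 went from 3.54 ± 0.075 to 227 ± 19.5 CPM, and gst-4 was at -1.73 (SE 0.203). Of 56 cytochrome P450 genes 18 rose and 8 fell (22 and 9 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation), including cyp-35B1 at 2.37 (SE 0.344). In the list of 11 tested intracellular pathogen response genes 5 rose (5 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation), among them the ubiquitin ligase components skr-5 at 3.94 (SE 0.272), skr-3 at 2.47 (SE 0.18) and cul-6 at 2.16 (SE 0.165). Of 40 insulin-like peptide genes and DAF-16 targets 13 rose and 2 fell (13 and 2 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation), with ins-7 at 2.06 (SE 0.248). Lysozymes went both ways, 6 of 11 higher and 4 lower (6 and 4 adjusted over the list alone), and camera did not call the list (adjusted p = 0.377); lys-3 rose by 5.18 (SE 0.24) and lys-1 by 3.59 (SE 0.191). The p38 pathway, which drives many infection genes, had 3 of 10 components higher (3 adjusted over the list alone), among them tir-1 at 1.28 (SE 0.151) and pmk-1 at 0.49 (SE 0.142), and camera did not call it (adjusted p = 0.267). Of 32 respiratory chain genes 7 fell (13 adjusted over the list alone; adjusted p = 0.287 with an estimated correlation), nuo-1 by 0.56 on the log2 scale (SE 0.149), and of 16 hypodermis markers 4 fell (4 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation), col-19 by 1.68 (SE 0.184).

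Without PA14 replicate 1 the count of lower genes was 544, and without PA14 replicate 2 there were 1277 higher and 575 lower genes.

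The second comparison asked what animals on z11 showed against OP50. On z11, 6 of 7 propionate shunt genes fell and 11 of 18 infection response genes rose (adjusted p = 0.495 and 0.242 with an estimated correlation). acdh-1 was at 14.8 ± 1.04 CPM on z11, a log2 fold change of -7.01 (SE 0.354, adjusted p = 3.69e-05), and acdh-2 fell from 90 ± 28.1 to 0.548 ± 0.084 CPM. C32H11.4 rose from 6.08 ± 0.61 to 572 ± 46.2 CPM, dod-24 to 1023 ± 28.8 CPM, and irg-3 by a log2 fold change of 5.05 (SE 0.175). The cysteine protease gene cpr-4 fell from 233 ± 0.181 to 7.67 ± 0.718 CPM. In all, 430 genes were higher and 648 lower, of which 249 were at least doubled and 400 at least halved. Of the called genes 39.9% were higher, against 19.7% with limma on log2(TPM + 1). That scaling moved the log2 fold changes of single genes by a median of -0.18.

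Of the 18 infection response genes, 11 rose and 1 fell on z11 (12 and 3 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation). sysm-1 rose from 14 ± 4.48 to 242 ± 48.6 CPM and irg-5 by a log2 fold change of 3.08 (SE 0.218); irg-1 rose by 0.93 (SE 0.223, adjusted p = 0.0452), and irg-4 was at 0.64 (SE 0.192, adjusted p = 0.0805). Of the 7 propionate shunt genes 6 fell and none rose (6 adjusted over the list alone; adjusted p = 0.495 with an estimated correlation), with hphd-1 at -4.79 (SE 0.198) and alh-8 at -1.45 (SE 0.166). Of the 15 methionine and S-adenosylmethionine cycle genes 8 fell and none rose (12 and 1 adjusted over the list alone; adjusted p = 0.242 with an estimated correlation), among them folt-2 at -3.87 (SE 0.184) and ahcy-1 at -1.77 (SE 0.21). Of 56 oxidative stress and glutathione genes 12 rose and 3 fell (15 and 3 adjusted over the list alone; adjusted p = 0.614 with an estimated correlation): the glutathione transferase genes gst-38 and gst-20 rose by 4.25 (SE 0.178) and 3.52 (SE 0.168). Of 16 hypodermis markers 7 fell (10 adjusted over the list alone; adjusted p = 0.614 with an estimated correlation), including wrt-10 at -1.89 (SE 0.205) and fbn-1 at -1.89 (SE 0.257). The ferritin gene ftn-1 fell by 2.94 on the log2 scale (SE 0.371).

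Of 24 lipid metabolism genes 9 were lower on z11, 3 higher and 12 not called (14 lower and 3 higher adjusted over the list alone; adjusted p = 0.614 with an estimated correlation): the acyl-CoA synthetase gene acs-2 was at -4.90 (SE 0.253) and the desaturase gene fat-5 at -2.07 (SE 0.206), while cpt-4 rose by 3.11 (SE 0.188). Of 80 cytosolic ribosomal protein genes 10 rose (24 higher and 1 lower adjusted over the list alone; adjusted p = 0.769 with an estimated correlation), among them rps-24 at 0.85 (SE 0.161). C-type lectins went both ways, 19 of 122 higher and 13 lower (23 and 17 adjusted over the list alone; adjusted p = 0.614 with an estimated correlation), with clec-47 at -5.31 (SE 0.276); the higher ones were over-represented, 19 against 3.61 expected. Fewer fbxa and receptor genes were called than on PA14: of 120 fbxa genes 6 rose and 3 fell (6 and 3 adjusted over the list alone), and of 187 nuclear hormone receptors 2 rose and 7 fell (2 and 7). Camera called the fbxa list upward (adjusted p = 0.0384) and the receptor list downward (adjusted p = 0.0122), each with adjusted p = 0.769 with an estimated correlation; nhr-114 was at -3.14 (SE 0.197). Without z11 replicate 1 the counts were 146 higher and 139 lower, and without OP50 replicate 1 and OP50 replicate 2 they reached 653 higher and 1278 lower respectively.

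The last comparison, PA14 against z11, set the 2 strains against each other directly. irg-1 was at 179 ± 3 CPM on PA14 and 2.18 ± 0.0563 CPM on z11, a log2 fold change of 6.36 (SE 0.211, adjusted p = 5.49e-06). clec-4 (6.13, SE 0.19), cld-1 (6.40, SE 0.291) and the P-glycoprotein transporter gene pgp-7 (6.77, SE 0.282) were also far higher on PA14. The collagen gene col-43 was at 0.897 ± 0.147 CPM on PA14 and 17.7 ± 3.02 CPM on z11, and D1086.3 at 18.9 ± 0.551 and 278 ± 23.4 CPM. There were 2422 genes higher and 1081 lower on PA14. Of the called genes 69.1% were higher, against 58.4% with the DESeq2 Wald test and 86% with limma on log2(TPM + 1). The latter moved the log2 fold changes of single genes by a median of 0.216.

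Of the 18 infection response genes 17 were higher on PA14 than on z11 and none lower (17 adjusted over the list alone; adjusted p = 0.218 with an estimated correlation). Of 187 nuclear hormone receptors 96 were higher and 3 lower (102 and 4 adjusted over the list alone), of 120 fbxa genes 67 and 3 (71 and 4), and of 56 cytochrome P450 genes 26 and 5 (27 and 6); each had adjusted p = 0.596 with an estimated correlation. Collagens were 34 lower and 7 higher of 120 (35 and 13 adjusted over the list alone; adjusted p = 0.596 with an estimated correlation), with col-98 at -3.31 (SE 0.22). Of 80 cytosolic ribosomal protein genes 21 were lower and 2 higher (36 and 2 adjusted over the list alone; adjusted p = 0.596 with an estimated correlation): rpl-11.1 was at -0.98 (SE 0.176) and rps-24 at -0.79 (SE 0.161), while rpl-25.1 and rpl-11.2 were higher. Of 15 intestine markers 11 were higher and 1 lower (11 and 1 adjusted over the list alone; adjusted p = 0.596 with an estimated correlation), including ifc-2 at 2.70 (SE 0.163) and the intestinal actin gene act-5 at 1.47 (SE 0.164). C-type lectins were 48 higher and 12 lower of 122 (56 and 16 adjusted over the list alone), and lysozymes 5 higher and 1 lower of 11 (6 and 1), each with adjusted p = 0.596 with an estimated correlation; lys-3 was at 4.72 (SE 0.237). acdh-1 (0.35, SE 0.284, adjusted p = 0.402) and hphd-1 (0.34, SE 0.175, adjusted p = 0.2) were not called. Without PA14 replicate 2 the counts were 1450 higher and 379 lower, and without OP50 replicate 1 there were 2011 lower genes.

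**Figure D2:**
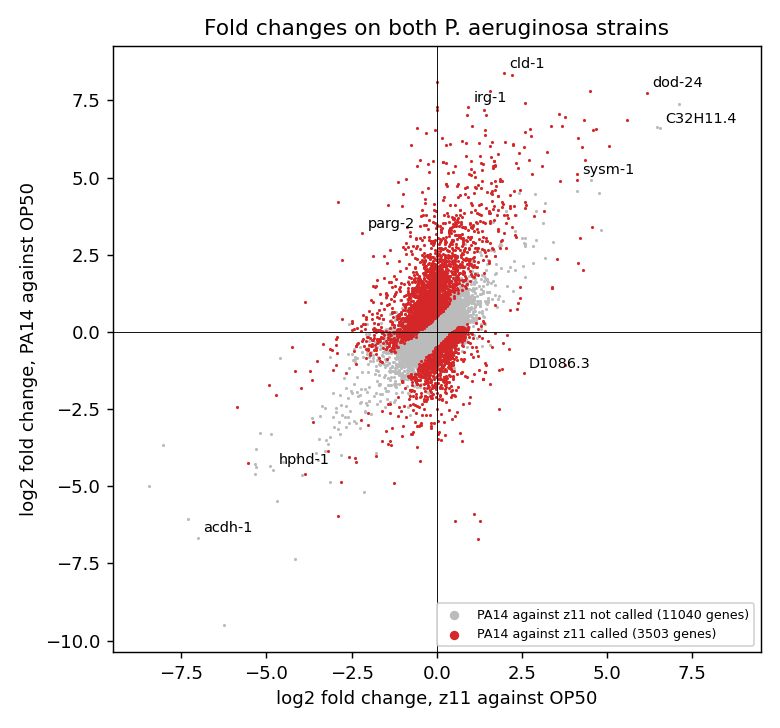
Log2 fold change on z11 against OP50 (horizontal) and on PA14 against OP50 (vertical) for the 14543 genes tested; red points are the 3503 genes called between PA14 and z11. acdh-1 and hphd-1 lie low on both axes, and irg-1 and cld-1 lie high on the PA14 axis.

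Requiring a call against both other groups left 1628 genes PA14-distinct and higher and 551 PA14-distinct and lower. The classes overlap: of the 264 genes higher on both strains than on OP50, 183 are also PA14-distinct, cld-1 and irg-1 among them. C50F7.5 led the higher genes, with 113 ± 7.6 CPM on PA14 and 1.22 ± 0.188 on OP50, followed by pgp-7, cld-1, irg-1 and clc-12. Y48E1B.8, T13F3.6 and col-43 led the lower ones. The z11-distinct genes were 132 higher and 296 lower: pud-3 was at 1480.5 ± 18.4 CPM on z11, 304 ± 58.5 on PA14 and 76.5 ± 40.1 on OP50, and cpr-4 and pgp-1 led the lower genes. Without PA14 replicate 2 there were 1043 PA14-distinct higher genes, and without z11 replicate 1 there were 18 higher and 36 lower z11-distinct genes.

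Both strains raised 264 genes and lowered 257 against OP50. Without z11 replicate 1 these counts were 135 and 101, and without PA14 replicate 1 and PA14 replicate 2 the lower count was 144 and 149. Among the shared genes C32H11.4 was at 590 ± 2.91 CPM on PA14 and 572 ± 46.2 CPM on z11, followed by dod-24, comt-2, irg-3 and F55G11.2; acdh-1, acdh-2, C09B8.4, clc-24 and hphd-1 led the lower genes. Of the genes higher on z11, 61.4% were also higher on PA14, and 13.6% the other way round. For lower genes these shares were 39.7% and 24.1%. Independent calls would give 57.4 genes higher in both and 47.6 lower in both, but calls against the same OP50 libraries are not independent. Simulations with no effect, which share the OP50 libraries in the same way, gave on average 0.15 genes higher in both and 0 lower in both. They held on average only 0.6 calls for PA14 and 0.95 for z11, so little overlap was possible. These simulations do not show how far the shared libraries add to the overlap of real effects. Across genes, which are not independent replicates, the 2 sets of fold changes correlated at r = 0.496. Both comparisons use the same OP50 libraries, and 20 simulations with no effect gave a mean r of 0.473 and a covariance of 0.0475, against an observed covariance of 0.349. The difference was 0.301. With a separate OP50 library for each comparison the covariance was lower, 0.255 and 0.234, and r was 0.386 and 0.327. The share of genes with the same sign in both comparisons went the other way, 63.5% against a simulated mean of 66.1%, so no similarity across all genes is claimed beyond the shared calls.

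**Figure D3:**
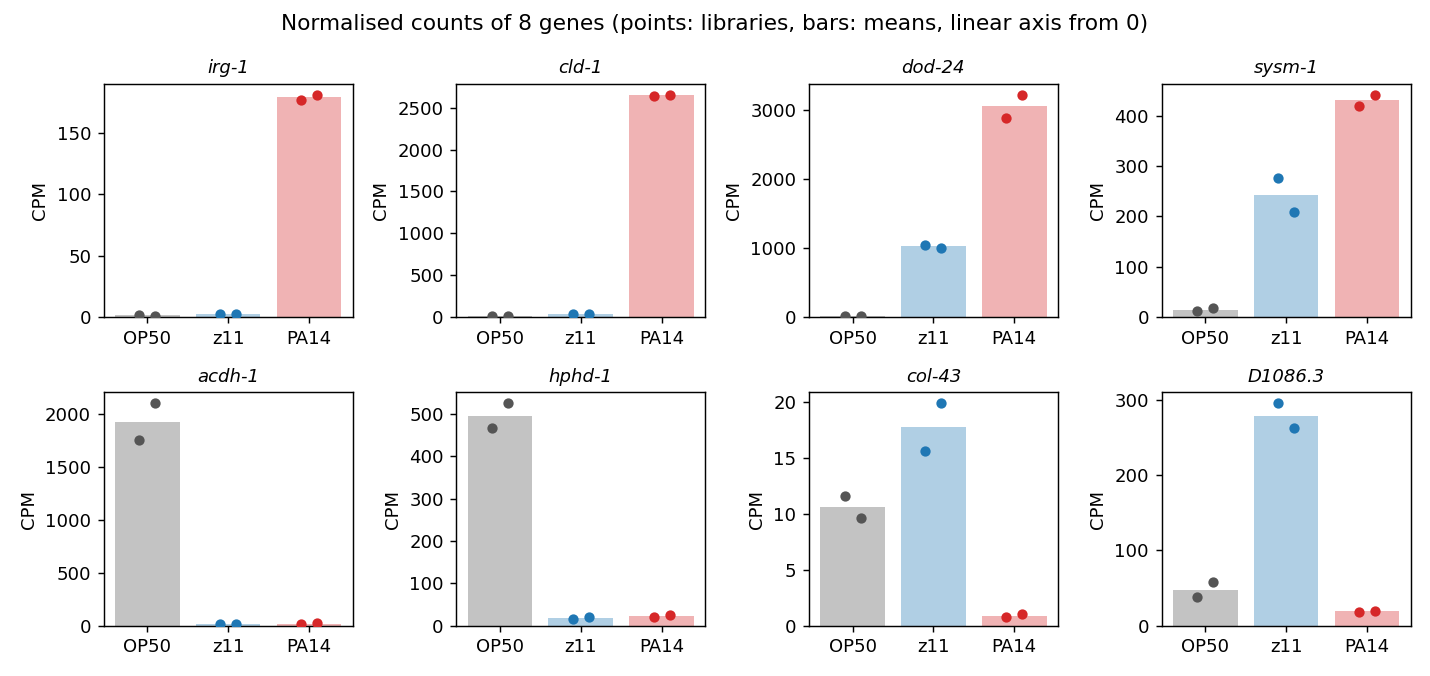
CPM of 8 genes on OP50, z11 and PA14, with each library as a point and the mean of 2 libraries as a bar on a linear axis from 0. irg-1 and cld-1 are high on PA14, dod-24 and sysm-1 are raised on both strains, acdh-1 and hphd-1 are low on both, and D1086.3 is highest on z11.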

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

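The test of the share of intestinal RNA, the count without identical gene copies, and the list medians on TPM and with an effective length offset, were chosen after the result was seen. Against OP50, 45 genes were higher on PA14 and lower on z11, and 19 were lower on PA14 and higher on z11, or 12 with identical gene copies counted once. The genes were selected for opposite signs, so that they were also called between PA14 and z11 adds nothing. The poly(ADP-ribose) glycohydrolase gene parg-2 was at 6.29 ± 0.633 CPM on OP50, 57.4 ± 3.37 on PA14 and 1.37 ± 0.0482 on z11. The log2 fold changes on PA14 and z11 were 2.34 (SE 0.241) and -2.77 (SE 0.294) for cyp-13A5 and 2.46 (SE 0.179) and -1.56 (SE 0.183) for pgp-6. In the other direction D1086.3 was at -1.33 (SE 0.216) and 2.55 (SE 0.219), and the hedgehog-related genes grd-4 and grd-14 at -1.58 (SE 0.247) and -2.32 (SE 0.205) on PA14. No technical explanation was tested for these genes.

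The libraries within groups split on oocyte transcripts in an average over the 3 groups, which does not show that each group did. On that average, the 25 germline and oocyte genes had a median log2 ratio of 0.553, longer against shorter mean fragment. A bias by transcript length would bring this within the range of random lists matched on effective length, -0.0447 to 0.222, and it lay above it. Those lists treat correlated genes as separate, so their range may be too narrow. Depth cannot be told apart from fragment length here: the longer-fragment library was the shallower one in each of the 3 groups, and thinning all libraries to the smallest total, which left the median at 0.557, keeps the ratios of abundant genes by construction. The design names no biological difference between replicates and none was tested; a difference in the stage or oocyte content of the animals stays open.

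Cytosolic ribosomal protein genes were lower on PA14 than on z11, with a median log2 fold change of -0.362 over 80 genes, of which 21 were called lower, 2 higher and 57 not (adjusted p = 0.596 with an estimated correlation, which was 0.395). Length-matched lists spanned -0.237 to 0.124, which argues against transcript length as the whole cause. Under 3 scalings the highest upper bound of the median was -0.188, but on log2(TPM + 1) the median was -0.12 (-0.243 to 0.0568), while the median of all genes was 0.226. The list therefore lay below the median gene on that scale too, and what the scaling leaves open is whether it fell below 0. The bounds, like the range of the length-matched lists, treat correlated genes as separate and may be too narrow. Without z11 replicate 2 the median was -0.55. On PA14 against OP50, 1 gene of the list was called higher and none lower, with a median of -0.086. Camera did not call the list there (adjusted p = 0.156). On z11 against OP50, 10 were called higher and none lower, with a median of 0.29. Camera called it higher there (adjusted p = 7.23e-05, and 0.769 with an estimated correlation). A fall on PA14 relative to OP50 was therefore not shown. PA14 against z11 compares the strains directly, and camera called the list lower there (adjusted p = 9.275e-07, and 0.596 with an estimated correlation). The cause of that difference was not tested further.

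Of 15 intestine markers, 9 were called higher on PA14 than on OP50, 1 lower and 5 not. Camera called the list higher (median 1.095, adjusted p = 0.000737, and 0.509 with an estimated correlation). A larger share of intestinal RNA would raise them alike, but 11 of 15 lay further than 2 standard errors from the list median, from -2.70 to 2.58, which argues against it as the whole cause. Other tissue lists were mixed: camera called hypodermis (median -0.46), muscle (-0.38) and germline markers (-0.41) lower, with adjusted p = 0.407, 0.509 and 0.758 with an estimated correlation, while neuron (median 0.26) and pharynx markers (0.53), which a larger intestinal share would also lower, lay above 0 and were not called (adjusted p = 0.214 and 0.186). The lowest lower bound of the intestine median under 3 scalings was 0.0137, just above 0, and 0.0649 under the scalings added later. A change in intestinal expression and a partial change of tissue share both stay open.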

How the results depend on the processing

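The labels do not say that equal numbers mark a pair. Deviations of same-numbered libraries correlated at -0.416 (OP50 and z11), 0.255 (OP50 and PA14) and -0.212 (z11 and PA14). These signs become alike if the z11 numbers are exchanged. On the third principal component OP50 replicate 1, z11 replicate 2 and PA14 replicate 1 were at -20.8, -22.9 and -10.7. The other library of each group was at 30.2, 14.4 and 9.79. The libraries thus share an axis across groups, whose source was not settled. The replicate block follows the numbers, so it sets z11 against this axis and does not adjust for it. With the replicate block, z11 against OP50 gave 196 higher and 260 lower genes, z11-distinct genes 29 and 96, genes shared by both strains 169 and 149, and 5 families for z11. The fragment length covariate, chosen after seeing the data because the libraries of each group split along it, gave 1769 lower genes for PA14 against OP50, 1669 higher and 2299 lower for z11 against OP50, 2338 lower for PA14 against z11, 889 and 1009 z11-distinct, 978 PA14-distinct lower, and 488 and 644 shared genes. It kept all 3008, 1078 and 3503 genes called without it; with the lengths exchanged within OP50, within z11 or within both, the calls were 2566 to 2983, 537 to 1353 and 2685 to 3513. Because it follows an axis found in these data, its larger counts are not stronger evidence. At a threshold of 0.01 the counts were 591 lower (PA14 against OP50), 155 and 184 (z11 against OP50), 1556 and 430 (PA14 against z11), 267 PA14-distinct lower, 16 and 57 z11-distinct, and 142 and 113 shared. Requiring a doubling or halving gave 629 lower, 249 and 400, 407 lower, 289 PA14-distinct lower, 44 and 140 z11-distinct, and 161 shared lower genes, in the same order. Both follow from the stricter rule, and the filter at 10 CPM, which tests fewer genes, gave 1188 higher (PA14 against OP50), 1556 higher (PA14 against z11) and 1059 PA14-distinct higher. The DESeq2 Wald test gave 766 and 1262 for z11 against OP50 and 334 z11-distinct higher; no filter gave 674 and 1330, with 270 and 462 z11-distinct. Library size alone gave 1033 lower for z11 against OP50 and 203 and 457 z11-distinct. log2(TPM + 1) gave 224 higher for z11 against OP50, 542 lower for PA14 against z11, 39 z11-distinct higher and 359 PA14-distinct lower; log2(TPM + 0.1) gave 246, 555 and 29, with 516 z11-distinct lower. With only the 2 groups compared, z11 against OP50 gave 211 and 333 and PA14 against z11 1677 lower. For these the cause was not tested. Counting identical gene copies once, added after seeing the data, gave 20, 8 and 23 over-represented families for PA14 against OP50, z11 against OP50 and PA14 against z11, from 22, 9 and 23; histones (both OP50 comparisons) and hsp genes were no longer among them against OP50. The correlation of both responses was 0.386 and 0.327 with separate OP50 libraries. With an estimated correlation, under which camera has less power here, 0 lists were called in each comparison, against 19, 15 and 16 with the preset one. fry called 18 for PA14 against OP50, 7 for z11 against OP50 and 19 for PA14 against z11.

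Leaving out 1 library leaves its group with a lone sample, assumed to vary like the others. Counts then ranged from 1277 to 1987 higher and 544 to 1348 lower for PA14 against OP50, 146 to 653 and 139 to 1278 for z11 against OP50, and 1450 to 2957 and 379 to 2011 for PA14 against z11. PA14-distinct genes ranged from 1043 to 1626 higher and 261 to 829 lower, z11-distinct from 18 to 304 and 36 to 486, and shared from 135 to 349 and 101 to 355. The correlation ranged from 0.348 (without z11 replicate 1) to 0.612 (without OP50 replicate 2), and lists called for z11 against OP50 from 9 to 15. The major sperm protein list for PA14 against OP50 was called as higher by camera (adjusted p = 0.0475, and 0.758 with an estimated correlation). None of its 27 tested genes was called. Without OP50 replicate 1 the list turned to the other direction in camera. Its median log2 fold change was then 0.0541, the lowest over the left-out libraries, and 1.25 without OP50 replicate 2, the highest. No named gene changed direction while called under any alternative run. The named genes lost 84 calls without PA14 replicate 2 and 72 without z11 replicate 1, the most of any setting, and 55 with the replicate block. With 2 libraries per group, 2-fold changes were recovered in 51% of simulated genes for PA14 against OP50, so genes not called are not shown to be unchanged.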

Other observations

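The count of histones with identical copies counted once was chosen after the result was seen. Smaller families not yet described also held more called genes than expected. On PA14 against OP50, 12 of 18 oac acyltransferase-like genes were higher (2.4 expected), 9 of 12 nspg genes (1.6 expected), 7 of 14 P-glycoprotein transporter genes (1.87 expected) and 14 of 40 glutathione transferase genes (5.34 expected), all over-represented in Fisher's exact test. UDP-glucuronosyltransferase genes went both ways, with 21 of 60 higher and 20 lower. On z11 against OP50, 12 of 40 glutathione transferase genes and 5 of 12 nspg genes were also higher (1.16 and 0.347 expected). P-glycoprotein genes went the other way there, with 5 of 14 lower (0.624 expected). With identical copies counted once, Fisher's exact test gave these 3 adjusted p = 2.16e-07, 0.000904 and 0.0113. Of 18 oac genes 3 were higher on z11, which was not over-represented (adjusted p = 0.178). On PA14 against z11, mitochondrial ribosomal protein genes were lower, 14 of 41 mrpl genes (3.05 expected) and 11 of 29 mrps genes (2.16 expected), and 11 of 37 histone genes were lower (2.74 expected) with identical copies counted once. No mrpl or mrps gene was called on PA14 against OP50. On z11 against OP50, 5 mrpl and 2 mrps genes were higher (1.19 and 0.84 expected). Neither was over-represented with identical copies counted once (adjusted p = 0.107 and 0.943 in Fisher's exact test). Vitellogenin vit-2 was at 9666 ± 3197 CPM on OP50, 12527 ± 332 on PA14 and 5859 ± 1409 on z11. It was not called on either strain against OP50. Of the 6 vitellogenins 2 fell on PA14 against OP50, and camera did not call the list (adjusted p = 0.214). On z11 against OP50 none was called, but 6 were lower when adjusted over the list alone. Camera called the list lower there, with a median log2 fold change of -0.73 (adjusted p = 0.0384, and 0.769 with an estimated correlation). On PA14 against z11, 2 were higher and 1 lower, and camera did not call the list (adjusted p = 0.997). The neuronal gene daf-7 was not called on either strain, with log2 fold changes of 0.12 (SE 0.244) on PA14 and -0.06 (SE 0.244) on z11.

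The PA14-distinct higher genes tended to be neighbours. Among 1627 such genes with a position, 463 pairs were adjacent among the tested genes, where 10000 random placements within chromosomes gave 200 on average (permutation p = 1e-04, one-sided, the smallest they can give). Leaving out pairs with the same family name left 369 pairs, where the highest of the placements had 234. Leaving out pairs from the same sequenced clone as well left 76 pairs, above the highest of the placements, 67. Shared regulation of neighbouring genes may explain this, but operons and duplicated genes with different names were not separated from it.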
